A study of Mus musculus with 6 samples.

How the data were processed

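Gene expression was measured by RNA sequencing of LSK cells, the lineage-negative, Sca1-positive, cKit-positive fraction of mouse bone marrow that holds hematopoietic stem cells and multipotent progenitors. The cells were sorted by flow cytometry from C57BL/6 mice with colitis induced by dextran sulfate sodium (DSS), called DIC in the labels, and from control mice. Per the labels' protocols, DSS was given at 2.5% over 5 days, RNA was extracted with TRIzol, and libraries were made with a SMART-Seq low-input kit and sequenced as read pairs on an Illumina NovaSeq instrument. The labels give 3 mice per group and 3 libraries per group. Nothing else in the labels describes the replication, so p-values measure the spread between these libraries.

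The authors deposited 1 table of TPM values with 56750 rows and 6 libraries, rounded to 2 decimals. The submitters' processing notes name fastp 0.19.5 for read trimming, HISAT2 2.1.0 for alignment, StringTie 2.1.2 and the build GRCm39, while the annotation release is not given in the sources used here. Each column summed to 1000000. TPM keeps no sequencing depth, so the depth behind each value is unknown and no counting interval could be given. As a description of yield, 20474 to 22720 genes lay above 0 TPM in a library. The rows included 1336 loci without an annotated gene, as StringTie names loci that it assembles, of which 657 were tested and which took 2.01% to 2.70% of a library's TPM. Because exact zeros in such a table can be failed estimates, a gene is described as listed at 0, with each library's value. StringTie divides reads among overlapping transcripts and near-identical genes, which makes values of such genes uncertain.

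Gene symbols came from the reference annotation of the earlier assembly GRCm38, matched by gene identifier. It gave a symbol to 52081 identifiers and none to 4669, which took 3.11% to 3.78% of TPM per library. No coordinates are reported, because the reference and the submitters' build differ. Chromosomes were used only to group genes. Of 833 entries in the fixed gene lists, 26 were matched through an older symbol and 34 found no row.

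Libraries were named DIC 1 to 3 and control 1, 2 and 4 after the numbers in the table's columns. The group of each column was clear, but columns 1 and 4 of the controls could not be assigned to single samples, since the title and description of 1 sample carry different numbers. No value column was left unused. No pair of libraries was a repeat of another, since the 15 pairwise correlations of log2(TPM + 1) over tested genes lay between 0.907 and 0.964.

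The comparison was DIC minus control. Genes with at least 1 TPM in at least 3 of the 6 libraries were tested, which left 13496. log2(TPM + 1) was fitted with limma 3.58.1 in R 4.3.3 with a mean-variance trend and group as the single term, and p-values were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates changes of low genes. SE is the moderated standard error and SD the spread of TPM over the 3 libraries of a group. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1, so none was run for single genes. The numbers of called genes and lists were set beside those of the other splits into 3 and 3, a test with the same limit that could not tell the grouping from chance.

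A total of 31 gene lists were fixed before the data were examined, covering blood lineages, the cell cycle, interferon and inflammatory signalling, metabolism, translation, antigen presentation, histones and other cell types of the marrow. Lists with at least 5 tested members, 30 of the 31, were tested with camera at a preset correlation of 0.01, with adjustment over the lists. An estimated correlation and fry, directional and mixed, were the alternatives. The count of members past the threshold is given over all genes and adjusted over the list alone. A list score is the mean log2(TPM + 1) of its tested members in a library. The table held no functional terms, so the planned test of such terms was not run.

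Named genes followed a rule fixed in advance. It took up to 12 genes per direction with the largest change among those past the threshold, with a mean of at least 5 TPM in the higher group, no overlap between groups and a symbol other than a predicted or clone name. Directions with fewer were filled to 6 by lowest p. It then took in each list up to 4 members past the threshold, or the 2 with the lowest p where none passed, and a fixed set of genes for the sort and the main lineages. Genes named outside it are said to have been chosen after their values were seen.

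The fit was tested on simulated data made from the real genes' means and spreads, with 200 of 13496 genes changed in each of 5 runs of the DIC and control design. It recovered 41.2% of genes with a simulated log2 change of 1, 80.1% at 2 and 88.5% at 3. Of 741 calls 45 were false, and 2 of 100 unchanged lists were called. The simulated genes varied independently and the lists were random, so the rate for lists does not carry over to genes that vary together. Alternatives set in advance varied the pseudocount, the filter, the scaling, the removal of mitochondrially encoded and ribosomal protein genes, the trend, library quality weights, a replicate block, the threshold, the list test and the library left out. Chosen after seeing the data were the removal of the neutrophil list, its score as a covariate and the removal of loci without an annotated gene. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.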

Results

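Cells sorted as LSK cells, per the labels, from 3 mice with DSS-induced colitis (DIC) and 3 control mice were profiled. The question was how intestinal inflammation alters gene expression in the stem and progenitor compartment of the bone marrow. The deposited TPM table gave values above 0 for 20474 to 22720 genes per library, and 13496 genes were tested. The first principal component held 43.8% of the variance. It placed the DIC libraries at 10.9 to 46.9 and the controls at -40.6, 6.02 and -53.2, so that control 2 lay next to the DIC libraries.

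In DIC, the nonclassical MHC class I genes H2-Q6 and H2-Q7 fell. As groups by camera with a preset correlation, interferon-gamma response and MHC class II genes were lower, and neutrophil, erythroid and histone genes higher. With an estimated correlation 0 lists were called (adjusted p = 0.623, 0.315, 0.623, 0.671 and 0.315 for these 5). Few single genes passed the test. With limma and Benjamini-Hochberg adjustment, 5 genes rose and 3 fell, against 5 and 1 after quantile normalization. At an unadjusted p under 0.05, 868 genes were higher and 1861 lower, together 2729, where 674.8 of 13496 would be expected by chance. The groups did not overlap for 956 genes with higher and 2486 with lower values in DIC, together 25.5% of tested genes, where chance gives 10%.

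H2-Q6 (ENSMUSG00000073409) measured 43.7 ± 4.83 TPM in DIC and 178 ± 27.8 in control (SD, n = 3 each), a log2 fold change of -2.0 ± 0.16 (SE) with limma adjusted p = 0.0187. H2-Q7 (ENSMUSG00000060550) measured 63.7 ± 7.37 and 241 ± 32.4 TPM (log2 fold change -1.90 ± 0.15, limma adjusted p = 0.0187). These genes are near-identical copies, so reads can be shared between them. H2-T22, another nonclassical class I gene, measured 12.8 ± 0.26 against 29.0 ± 2.14 TPM and did not pass (limma adjusted p = 0.0533). Neither did H2-K1, a classical class I heavy chain, at 936 ± 54.0 against 1821 ± 142 TPM, nor Tap1, a subunit of the peptide transporter, at 41.7 ± 0.79 against 70.2 ± 3.43 TPM (both limma adjusted p = 0.201). In all of these genes every DIC library lay below every control library, which the rule for named genes required of them.

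Among the genes that rose, Tanc2 (ENSMUSG00000053580), which encodes a scaffold protein, measured 26.6 ± 8.15 TPM in DIC and 1.2 ± 0.73 in control (log2 fold change 3.65 ± 0.32, limma adjusted p = 0.0206). The immunoglobulin kappa variable segment Igkv9-120 was at 14.9, 14.5 and 7.83 TPM in DIC 1 to 3, at 0.56 in control 2 and listed at 0 in controls 1 and 4 (limma adjusted p = 0.0206). The mitochondrially encoded mt-Nd4l, which overlaps mt-Nd4, was at 27.9, 75.0 and 17.9 TPM in DIC and listed at 0 in all 3 controls (limma adjusted p = 0.0206), whereas 12 of the 13 mitochondrially encoded genes had negative fold changes. The predicted genes Gm37375 and Gm14388, named after their values were seen, were also listed at 0 in all 3 controls. The small nucleolar RNA gene Snora9 was listed at 0 in all 3 DIC libraries and at 17.1, 57.1 and 111 TPM in controls 1, 2 and 4 (limma adjusted p = 0.046). The rule for named genes added 3 more immunoglobulin variable segments, which did not pass the threshold (limma adjusted p = 0.0546, 0.117 and 0.212). Igkv8-30 was at 39.1, 9.93 and 15.4 TPM in DIC and at most 0.51 in a control, Ighv9-3 at 10.1, 3.98 and 6.36 against at most 0.57, and Iglv2 at 6.90, 4.58 and 18.6 against at most 0.52.

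The number of called genes depended on single libraries. Without control 2, 530 genes were higher and 1141 lower, the 8 genes above among them. Leaving out DIC 1 or control 4 left 0 calls by limma (1239 and 1458 genes at an unadjusted p under 0.05), while 16 rose and 4 fell without DIC 2 and 3 rose and 3 fell without control 1.

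**Figure D1:**
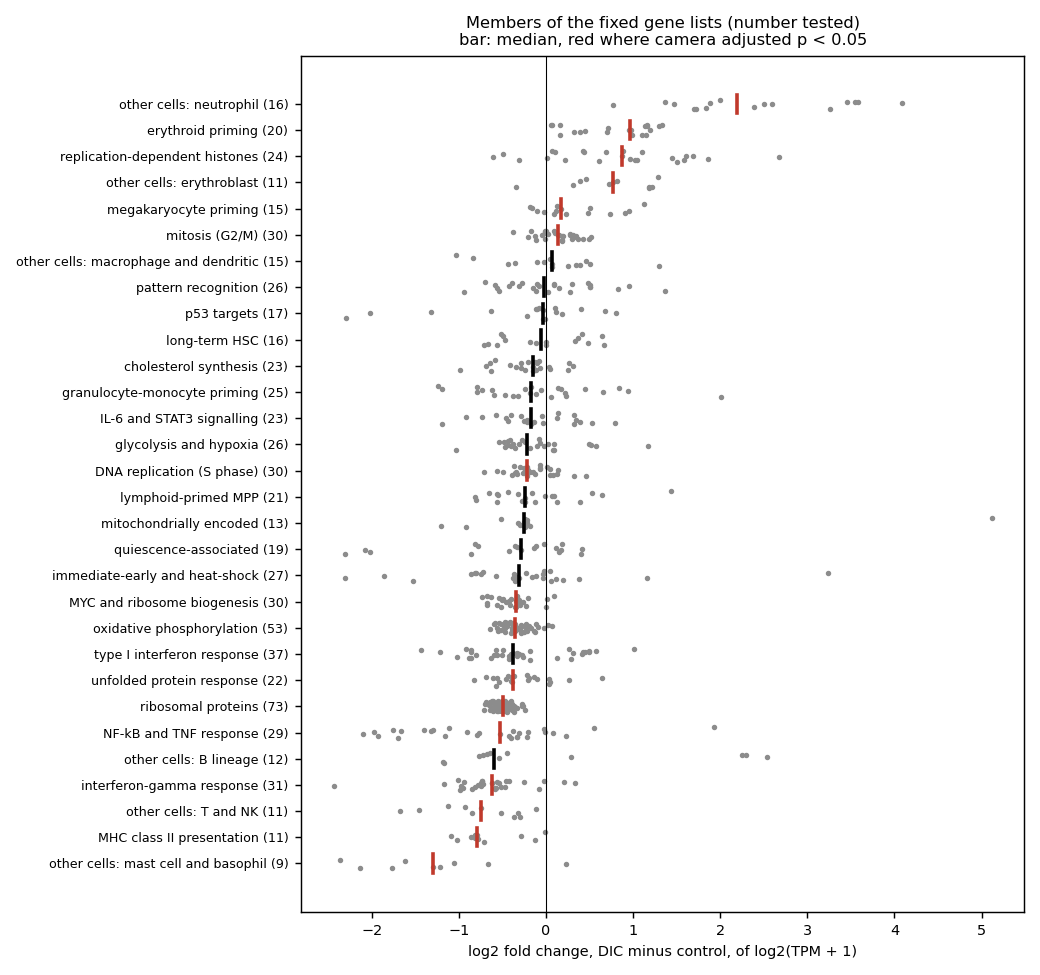
Log2 fold change (DIC minus control, log2(TPM + 1) scale, horizontal axis) of each tested member of the fixed gene lists (grey points, 1 row per list with the number tested), with the list median as a bar, red where camera's adjusted p is below 0.05. The neutrophil list has the highest median, 2.19, and the mast cell and basophil list the lowest, -1.30. The mitochondrially encoded point at the far right is mt-Nd4l, listed at 0 in all controls.

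Of 30 fixed lists, camera with a preset correlation called 6 higher and 10 lower in DIC. With an estimated correlation it called 0, and in other splits of the same 6 libraries the preset test called 8 to 16 lists, so each direction below describes these libraries. Directional fry called 1 list, MHC class II presentation, and mixed fry called 4.

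Neutrophil transcripts were far more abundant in DIC. All 16 members of the neutrophil list had positive fold changes, with a median of 2.19 (camera adjusted p = 8.0e-12, adjusted p = 0.623 with an estimated correlation), 0 passed over all genes and 16 rose when adjusted over the list alone. Ltf, which encodes the granule protein lactoferrin, measured 2706 ± 504 TPM in DIC against 660 ± 698 in control (SD, n = 3), and the neutrophil surface marker Ly6g 207 ± 149 against 22.8 ± 22.6. The list took 22.8%, 15.6% and 19.1% of all TPM in DIC 1 to 3 and 4.26%, 12.6% and 3.03% in controls 1, 2 and 4. Control 2 was therefore close to the DIC range. S100a8 and S100a9, chosen after their values were seen, together took 11.5% to 17.5% in DIC, 9.46% in control 2 and 3.24% and 2.38% in controls 1 and 4. The granulocyte-monocyte priming list, which covers earlier genes of this lineage, had a median of -0.17 (camera adjusted p = 0.982), and Mpo, the myeloperoxidase gene, measured 11063 ± 1217 against 12418 ± 772 TPM. Members of that list moved both ways, so its median does not show them unchanged. Irf8 measured 61.8 ± 13.4 against 146 ± 46.3 TPM and Cd33 42.4 ± 22.5 against 9.78 ± 5.92. Both separated the groups without overlap but did not pass (limma adjusted p = 0.212 each). Without control 2, 5 members were higher and 5 lower over all genes.

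Erythroid genes were higher, mainly in DIC 1 and DIC 3. All 20 members of the erythroid priming list had positive fold changes (median 0.96, camera adjusted p = 4.7e-09, adjusted p = 0.671 with an estimated correlation), with 0 past the threshold over all genes and 10 adjusted over the list alone. Tspo2 measured 19.1 ± 6.04 against 8.05 ± 2.73 TPM and Ank1, which encodes the membrane-skeleton protein ankyrin-1, 2.88 ± 1.39 against 0.61 ± 0.13. The erythroblast list of hemoglobin-making cells rose by a median of 0.77 (camera adjusted p = 0.00059, adjusted p = 0.71 with an estimated correlation), 0 members passing over all genes or adjusted over the list alone. The scores of both lists were highest in DIC 1 and DIC 3, and DIC 2 overlapped the controls. It scored 4.83 on erythroid priming, below control 2 at 4.85. On the erythroblast list it scored 3.26, below controls 1 and 4 at 3.48 and 3.57. The erythroblast median was 0.303 without DIC 1 and 1.27 without DIC 2. The megakaryocyte priming list rose by a median of 0.18 (camera adjusted p = 0.0029, adjusted p = 0.71 with an estimated correlation), again with 0 members past either threshold. Its member Cd9 measured 241 ± 33.3 against 130 ± 56.7 TPM. Its median was 0.35 without control 2, and the call ended without control 1 (median 0.082, camera adjusted p = 0.0707) and with a filter of 5 TPM (0.096, 0.0666). With the neutrophil score as a covariate, an alternative chosen after seeing the data, the erythroid, megakaryocyte and erythroblast medians were -0.183, -0.016 and -0.065.

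Histone and mitotic genes were higher, replication genes slightly lower. Of 24 tested replication-dependent histone genes, whose messages mostly lack poly(A) tails, 21 had positive fold changes (median 0.88, camera adjusted p = 1.1e-08, adjusted p = 0.315 with an estimated correlation), with 0 past the threshold over all genes and 8 adjusted over the list alone. Hist1h4m measured 126 ± 3.80 against 69.0 ± 10.8 TPM. The more abundant histone gene Hist1h2ap, chosen after its values were seen, went the other way, at 2434 ± 383 against 3534 ± 1130. The list held 54 entries, of which 24 could be tested. The mitosis list rose by a median of 0.14 (camera adjusted p = 0.0023, adjusted p = 0.71 with an estimated correlation), with Top2a at 131 ± 7.92 against 103 ± 5.65 TPM and the proliferation marker Mki67 at 49.5 ± 4.91 against 36.6 ± 4.90. The DNA replication list fell by a median of 0.22 with 22 of 30 members negative (camera adjusted p = 0.044, adjusted p = 0.751 with an estimated correlation). Neither list had a member past the threshold over all genes or adjusted over the list alone, and without control 2 neither was called (camera adjusted p = 0.0759 for mitosis and 0.0531 for replication). The mitosis median was 0.085 without DIC 1 and 0.066 without control 4. The replication call also ended without DIC 1 (0.226), without control 1 (0.253) and in 8 settings of the scaling, filter, fit or genes kept, with camera adjusted p from 0.0503 to 0.93.

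Antigen-presentation genes were lower. In the interferon-gamma response list 29 of 31 members had negative fold changes, with a median of -0.62 (camera adjusted p = 1.1e-08, adjusted p = 0.623 with an estimated correlation), 0 past the threshold over all genes and 13 adjusted over the list alone. The list held H2-K1 and Tap1 above, and 19 members separated the groups without overlap. All 11 tested members of the MHC class II list were negative, with a median of -0.79 (camera adjusted p = 3.3e-05, adjusted p = 0.315 with an estimated correlation, directional fry adjusted p = 0.04), 0 past the threshold over all genes and 7 adjusted over the list alone. H2-DMa and H2-DMb1, the chains of a peptide-loading molecule, measured 64.1 ± 11.5 against 137 ± 16.1 TPM and 29.1 ± 2.68 against 52.3 ± 7.24. Control 2 sat with the other controls on this list, at a score of 5.37 beside 5.17 and 5.39, against 4.64 to 4.65 in DIC. The type I interferon list, with a median of -0.37, was not called (camera adjusted p = 0.585), and its scores ranged from 3.12 to 4.70 over the controls. It was called lower without control 1 (median -0.671, camera adjusted p = 0.00373), while without control 4 its median was 0.135 (0.0652).

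**Figure D2:**
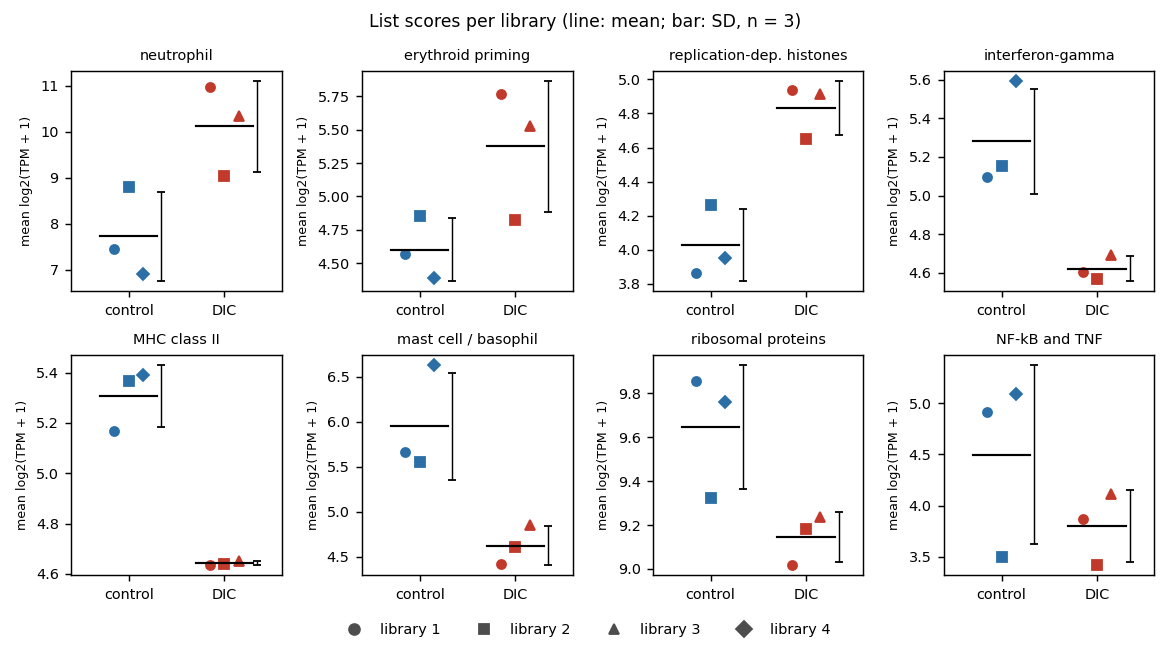
Mean log2(TPM + 1) of the tested members of 8 gene lists (vertical axes) in each library, with control in blue and DIC in red, marker shape giving the library number, the line the group mean and the bar the SD (n = 3). On the MHC class II list the DIC libraries lie at 4.64 to 4.65 and the controls at 5.17 to 5.39, while on the neutrophil list control 2 lies at 8.81 beside DIC 2 at 9.04.

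NF-kB and TNF response genes were lower in DIC and in control 2. The NF-kB and TNF list fell by a median of 0.53 with 25 of 29 members negative (camera adjusted p = 0.0018, adjusted p = 0.728 with an estimated correlation). No member passed over all genes (0) or adjusted over the list alone (0), and 14 were lower over all genes without control 2, where the median was -1.01. With the neutrophil score as a covariate the median was -0.079 and the list was not called (camera adjusted p = 0.874). Its scores were 3.41 to 4.11 in DIC, 3.49 in control 2 and 4.92 and 5.09 in controls 1 and 4. The immediate-early and heat-shock list, which includes dissociation-induced genes, was also low in DIC 1, DIC 2 and control 2 (4.54, 4.46 and 4.29) but not in DIC 3 (5.63). Icam1, an adhesion molecule, measured 6.53 ± 1.02 against 19.96 ± 7.94 TPM.

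Translation and respiration genes were slightly lower. All 73 ribosomal protein genes had negative fold changes (median -0.50, camera adjusted p = 1.5e-16, adjusted p = 0.71 with an estimated correlation), as did 51 of 53 genes of oxidative phosphorylation (median -0.36, camera adjusted p = 1.1e-08, adjusted p = 0.71 with an estimated correlation) and 27 of 30 of MYC and ribosome biogenesis (median -0.35, camera adjusted p = 1.2e-05, adjusted p = 0.71 with an estimated correlation). The unfolded protein response list fell by a median of 0.38 (camera adjusted p = 0.0184, adjusted p = 0.728 with an estimated correlation). These 4 lists had 0 members past the threshold over all genes and 0 adjusted over the list alone; without control 2, 63 ribosomal and 28 respiratory genes were lower over all genes. With the neutrophil score as a covariate none of the 4 was called, with medians of -0.13, -0.097, -0.094 and -0.092 in the order above (camera adjusted p = 0.739, 0.93, 0.874 and 0.874). The MYC median was -0.215 without control 1 and -0.529 without control 2. The size of these differences depends on the scaling. The median of all genes was -0.08, and it moved to 0.10 when the neutrophil list was removed and TPM rescaled, which left ribosomal proteins at -0.29 and oxidative phosphorylation at -0.15. After quantile normalization oxidative phosphorylation and the unfolded protein response were no longer called (camera adjusted p = 0.0708 and 0.408), and the latter was not called without DIC 1 (median -0.247, camera adjusted p = 0.0575), without control 1 (-0.249, 0.245) or with a filter of 5 TPM (-0.389, 0.0661).

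Markers of some other marrow cells were lower. In the mast cell and basophil list 8 of 9 members had negative fold changes, with a median of -1.30 (camera adjusted p = 0.0005, adjusted p = 0.671 with an estimated correlation), 0 past the threshold over all genes and 8 adjusted over the list alone. The basophil proteases Prss34 and Mcpt8 measured 170 ± 38.6 against 1026 ± 707 TPM and 125 ± 27.8 against 636 ± 434. All 11 tested T and NK cell markers were negative (median -0.75, camera adjusted p = 0.0053, adjusted p = 0.71 with an estimated correlation), with 0 past either threshold. Their median was -0.484 without control 4, and they were not called with the neutrophil score as a covariate (camera adjusted p = 0.0857). The B lineage list (median -0.60, camera adjusted p = 0.687) and the macrophage and dendritic cell list (median 0.06, camera adjusted p = 0.466) were not called, and too few endothelial and stromal genes were expressed for a test. With 1 library left out, the B lineage median ran from -0.884 without control 1 to -0.249 without control 4.

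**Figure D3:**
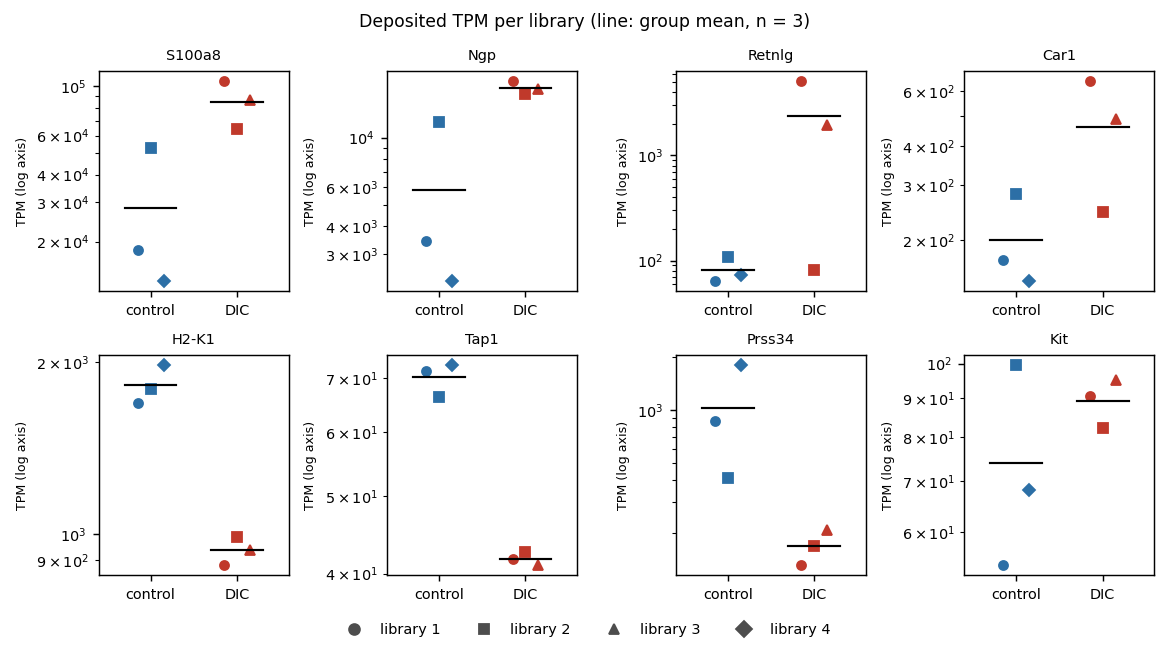
Deposited TPM (vertical log axes) of 8 genes in each library (S100a8, Ngp, Retnlg and Car1 chosen after their values were seen), with control in blue, DIC in red, marker shape for the library number and the line at the group mean (n = 3). Retnlg reaches 5102 and 1953 TPM in DIC 1 and DIC 3 and 81.4 in DIC 2, and H2-K1 lies below 989 TPM in DIC and above 1696 in control.

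Genes of the sort and of stem cells did not pass the test. Kit measured 89.4 ± 6.57 against 74.0 ± 23.2 TPM and Ly6a, which encodes Sca1, 19.4 ± 4.14 against 34.2 ± 15.2. Among tested genes, Ly6a ranked at percentiles 52.1 to 78.2 over the libraries, Kit at 79.2 to 89.4 and the granulocyte-monocyte gene Mpo at 99.95 to 99.98. In every library, controls included, granulocyte transcripts far exceeded those of the sort. Mpo was at 10026 to 13183 TPM and S100a8, chosen after its values were seen, at 13283 to 105476, against 15.5 to 49.9 for Ly6a. The values themselves therefore do not show a mainly LSK population, and the differences may not be those of LSK cells. The sort is known from the labels alone, and bulk values cannot place the differences in stem cells or multipotent progenitors. Cd34 was at 83.9 ± 17.5 against 119 ± 14.8 TPM, Flt3 at 16.4 ± 2.25 against 20.7 ± 7.14, and Cd48, a marker of multipotent progenitors, at 149 ± 10.7 against 238 ± 23.5 (log2 fold change -0.67 ± 0.13, limma adjusted p = 0.212). Procr and Slamf1 lay near the filter, at 1.6 ± 0.57 against 1.78 ± 1.48 and 0.98 ± 0.19 against 1.02 ± 0.11 TPM, and Slamf1 was not tested. The lineage factors Spi1, Cebpa and Gata1 measured 197 ± 16.6, 16.9 ± 2.08 and 25.6 ± 6.02 TPM in DIC against 213 ± 17.1, 21.3 ± 3.01 and 20.4 ± 5.99.

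The long-term HSC and lymphoid-primed lists had medians of -0.06 and -0.24 (camera adjusted p = 0.941 and 0.687). The lymphoid-primed median ran from -0.213 without control 1 to -0.094 without control 2. The remaining lists were not called by camera at the preset correlation in the fit of all 6 libraries with the filter of 1 TPM and group as the single term, and other settings that called some are given with the alternatives. Medians were -0.29 for quiescence-associated genes, -0.04 for p53 targets, -0.31 for immediate-early and heat-shock genes, -0.18 for IL-6 and STAT3 signalling, -0.03 for pattern recognition, -0.22 for glycolysis and hypoxia, -0.15 for cholesterol synthesis and -0.25 for mitochondrially encoded genes, with camera adjusted p between 0.0988 and 0.941. With 1 library left out, the quiescence-associated median ran from -0.509 to -0.061, IL-6 and STAT3 signalling from -0.296 to -0.091, glycolysis and hypoxia from -0.2765 to -0.092, immediate-early and heat-shock genes from -0.702 to -0.162, and mitochondrially encoded genes from -0.623 to -0.045. Also with 1 left out, immediate-early and heat-shock genes were called lower without control 2 (median -0.702, camera adjusted p = 0.00914) and without DIC 3 (-0.571, 0.00945), mitochondrially encoded genes without DIC 2 (-0.623, 0.00116) and cholesterol synthesis without control 4 (-0.186, 0.0351). For pattern recognition and p53 targets camera's direction was up, opposite to the median, and the means of the B lineage and mitochondrially encoded lists, 0.10 and 0.018, were opposite in sign to their medians.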

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

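Removal of the neutrophil list, its score as a covariate and removal of loci without an annotated gene were chosen after seeing the data. The counts of called genes, 5 higher and 3 lower, were fragile. Genes higher numbered 2 with a pseudocount of 0.1, 3 with 5 and 8 with library quality weights or a threshold of 0.10. Genes lower numbered 1 after quantile normalization. Without a filter both counts were 0 by limma (28869 genes tested, 3241 at an unadjusted p under 0.05), and likewise with the neutrophil score as a covariate (305 at an unadjusted p under 0.05). Leaving out 1 library at a time gave 0 to 530 higher and 0 to 1141 lower, the highest without control 2 and the lowest without DIC 1 and without control 4. H2-Q6 and H2-Q7 kept their direction in every alternative and lost the threshold without a filter, without DIC 1, without control 4, with the replicate block and with the covariate, at log2 fold changes of -1.998 to -1.806 and -1.946 to -1.817, and H2-Q7 also after quantile normalization (-1.724, limma adjusted p 0.0545). The replicate block gave 3 genes higher and 5 lower, sharing 1 and 0 with the fit without it. Only the numbers 1 and 2 occur in both groups, and the deviations of equally numbered libraries correlated at -0.07 and -0.10. These 2 values gave no sign of pairing but cannot exclude it, and control 1 could not be assigned to a single sample. Lists higher and lower, 6 and 10, fell to 0 and 0 with an estimated correlation and to 0 and 1 by directional fry, and were 4 and 6 with the covariate. In that fit 7 of the 10 lower lists lost their call, namely DNA replication, NF-kB and TNF, unfolded protein response, oxidative phosphorylation, MYC and ribosome biogenesis, ribosomal proteins, and T and NK, and so did the neutrophil list itself (median 0.148, camera adjusted p = 0.225). Interferon-gamma response (-0.478), MHC class II (-0.648), mast cell and basophil (-0.799), histones (0.439) and mitosis (0.029) were still called there. DNA replication lost its call with a filter of 5 TPM (camera adjusted p = 0.155), median-ratio scaling (0.177), quantile normalization (0.93), no trend (0.075), library quality weights (0.0561), the neutrophil list removed (0.48), the covariate (0.874), loci without an annotated gene removed (0.0503), and without DIC 1, control 1 or control 2. Uncalled before, cholesterol synthesis was called lower without a filter (0.00272), with the replicate block (0.0294) and with the covariate (0.0337), immediate-early genes with the block (0.0134), mitochondrially encoded genes by mixed fry (0.0203), and the long-term HSC and lymphoid-primed lists with the covariate (0.00198 and 0.00842). The other alternatives gave 5 to 7 higher and 7 to 12 lower. The cause of these changes was not tested. TPM keeps no depth, so its effect on low genes cannot be judged.

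Most results that changed sign were uncalled before. With a pseudocount of 5, Procr was at -0.021. Without a filter, pattern recognition was at 0.021. After median-ratio scaling, pattern recognition was at 0.054 and p53 targets at 0.051. After quantile normalization, Procr was at -0.102, Spi1 at 0.090, granulocyte-monocyte priming at 0.0145 and pattern recognition at 0.0147. Procr was at -0.026 without mitochondrial and ribosomal protein genes and at -0.0014 without loci lacking an annotated gene. With library quality weights, Pdgfrb was at 0.114, the long-term HSC list at 0.207 and p53 targets at 0.075. With the replicate block, Procr was at -0.327, pattern recognition at 0.182, the macrophage and dendritic list at -0.159 and the type I interferon list at 0.137 (camera adjusted p = 0.0438). By directional fry, p53 targets pointed opposite to camera (adjusted p = 0.667). With single libraries left out, the ranges were -0.204 to 0.407 for Procr, -0.378 to 0.154 for Pdgfrb, -0.276 to 0.267 for long-term HSC, -0.671 to 0.135 for type I interferon, -0.218 to 0.089 for pattern recognition, -0.149 to 0.049 for p53 targets and -0.104 to 0.276 for macrophage and dendritic. With the neutrophil list removed, Mpo was at 0.0365, Spi1 at 0.093, and the lists long-term HSC at 0.041, granulocyte-monocyte priming at 0.0365, pattern recognition at 0.156, p53 targets at 0.126 and cholesterol synthesis at 0.032. With the neutrophil score as a covariate, Cd52 was at -0.099, Pfkfb4 at -0.0215, Mif at 0.041, Jchain at -0.305, Kit at -0.206, Procr at -1.17, Mpo at 0.099 and Gata1 at -0.505. Uncalled lists that reversed in that fit were granulocyte-monocyte priming at 0.0185, macrophage and dendritic at -0.072, and immediate-early and heat-shock at 0.282 and mitochondrially encoded at 0.296, which were called in that direction (camera adjusted p = 0.0174 and 0.000421). The called lists megakaryocyte priming at -0.016, erythroid priming at -0.183 and erythroblast at -0.065 reversed there too. The score and the group overlap strongly, so this fit separates them poorly.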

Other observations

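Chosen after the results were seen were the tests of control 2, of all other marrow cells alike, of dilution in the MHC class II list and of progenitor genes as a reference. The predictions for a fixed granulocyte source, for shared H2 reads, for dilution in the interferon-gamma list and for the other splits were written beforehand. The bound for excluding dilution in that list was raised after its result was seen. The genes of the granulocyte ratio, Ltf aside, are among those chosen after their values were seen. Genes named here outside the fixed rule, which are Ngp, Camp, Lcn2, the late neutrophil genes, Ctsg, Prtn3, Elane, Hbb-bs, Igha, Igkc and Gm28437, were chosen after their values were seen.

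Neutrophil genes of different stages parted within the DIC group. Secondary granule genes (Ngp, Camp, Ltf, Lcn2) were high in every DIC library, with Ngp at 17917, 15596 and 16508 TPM in DIC 1 to 3, 11714 in control 2 and 3448 and 2272 in controls 1 and 4. Genes of late neutrophils (Retnlg, Mmp8, Mmp9, Cxcr2, Ccl6, Il1b and Csf3r) had mean log2 values of 8.54 and 7.40 in DIC 1 and DIC 3, 4.52 in DIC 2 and 3.88 to 4.62 in the controls, though Csf3r and Mmp9 in DIC 2, at 100 and 28.8 TPM, were above every control. Retnlg stood at 5102 and 1953 TPM there, at 81.4 in DIC 2 and at 63.7 to 109 in the controls, and Mmp8 at 562 and 197 against 13.3 in DIC 2 and at most 14.6 in a control. Primary granule genes had mean log2 values of 12.2 to 12.8 throughout, though members differed. Ctsg and Prtn3 were lower in DIC (log2 fold change -0.63 and -0.47), Ctsg without overlap between groups, while Mpo and Elane changed little (-0.17 and -0.055). None of the 15 genes passed the test over all genes. Other transcripts of mature marrow cells followed the same libraries: the beta-globin gene Hbb-bs was at 192 and 111 TPM in DIC 1 and DIC 3 against 32.5 to 44.7 elsewhere, and Igha, the constant region of IgA, at 139 and 35.3 against 1.48 to 7.03 elsewhere.

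Immunoglobulin variable segments above 0 TPM numbered 180, 94 and 147 of 348 in DIC 1 to 3 and 61, 109 and 68 in controls 1, 2 and 4. Igkc was at 631, 165 and 292 TPM in DIC and 45.0, 234 and 25.3 in the controls, so control 2 lay within the DIC range. Immediate-early and heat-shock genes followed no group, with list scores of 4.29 to 4.54 in DIC 1, DIC 2 and control 2 and of 5.54 to 5.63 in DIC 3, control 1 and control 4. A transcript of a mitochondrial pseudogene, Gm28437, took 9955 to 24984 TPM per library, and its reads can be shared with the mitochondrial genes.

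Neutrophil transcripts were higher in DIC although the sort for LSK cells would remove mature neutrophils. A lower share of the sorted progenitors, with all other marrow cells alike, would raise every list of other cells. The mast cell and basophil median was -1.3, but that list shares Gata2 with the long-term HSC list, so progenitors may express its genes too. The T and NK median was -0.75 at low levels, with scores of 1.21 to 2.76 over the libraries. These lists therefore leave that explanation undecided. A single granulocyte source of fixed composition would keep the ratio of late to secondary granule genes alike, but it ranged over 3.75 on the log2 scale. The genes of this ratio, Ltf aside, were chosen after their values were seen, so the range describes these libraries and does not exclude such a source. Of the 7 late genes 4 are also in the fixed neutrophil list and 1 in the granulocyte-monocyte list, as are all 4 secondary granule genes in the former. Open hypotheses, not separable in bulk RNA, are granulocytes or their RNA carried through the sort in amounts that differ between libraries, and granule transcripts made by progenitors that may be driven to the granulocyte lineage by colitis.

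Antigen-presentation transcripts were lower in DIC. Shared reads between near-identical H2 genes, or an H2 variant on chromosome 17, are argued against as the whole cause for the interferon-gamma list. Its 24 members on other chromosomes (by GRCm38) had a median of -0.62, 22 of them negative, and DIC scores of at most 3.87 against at least 4.21 in control. Not all of these members act in antigen presentation, so for the H2 genes themselves such a cause stays open. Dilution by granulocyte RNA is argued against, though weakly, for the MHC class II list. The group term of that list was -0.665 ± 0.071 (SE) and, with the neutrophil score as a covariate, -0.685 ± 0.15 (95% interval -1.15 to -0.22). That fit had 3 residual degrees of freedom, the score and the group overlap strongly, and the list was chosen after its scores were seen. The score is a mean of log2 values and does not measure the share of granulocyte RNA. For the interferon-gamma list dilution stays open in part: the term was -0.66 ± 0.16, and -0.484 ± 0.31 with the covariate. With the neutrophil list removed, the median was -0.52 against 0.10 for all genes, not within the 0.2 predicted for dilution. That removal rescales all remaining genes of a library by a common factor, so it moves both medians together and cannot decide. Control 2 and DIC 2, closest in neutrophil score, differed by 0.58, barely over the bound of 0.54 set beforehand, which rests on single libraries. By that bound alone dilution would have been argued against, and the bound was raised after this result was seen. Against progenitor genes, which such RNA would dilute too, the list was lower in DIC by 0.61 ± 0.30 (long-term HSC, groups overlapping), 0.54 ± 0.19 (lymphoid-primed, separate) or 0.57 ± 0.23 (both, lowest control 0.65 and highest DIC library 0.62), 3 references tried after the scores were seen. Lower interferon-gamma signalling or a changed mix of progenitors in colitis may also account for the pattern and was not tested.

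Control 2 lay towards the DIC libraries on several lists. Its position was -0.137 on the MHC class II list, where 0 is the mean of controls 1 and 4 and 1 the mean of DIC. A DIC library under a wrong label would lie near 1, but that list was chosen after the scores were seen. Positions were 0.269 on the interferon-gamma list and 1.255 on the NF-kB and TNF list. They were 1.234 and 1.134 on the quiescence-associated and p53 lists, which were not called. Over the called lists they ran from -0.443 (erythroblast) to 1.255. Histones were at 0.384 and mast cells and basophils at 0.389, but ribosomal proteins at 0.729 and oxidative phosphorylation at 0.817. Those calls counted control 2 as a control, which favours positions below 1, so they cannot decide. A wrong label for control 2 is therefore not excluded. A larger share of granulocyte RNA may account for its neutrophil list, at position 0.553, but cannot be told apart from more such transcripts per cell. The same RNA is argued against for the NF-kB and TNF list, which lay 1.51 below the other controls (difference -1.51 on the log2 scale). Differences in handling or between mice stay open and untested.

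The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. With the real split counted, 2 splits gave at least the real 8 called genes, the highest other being 13 with DIC 1, DIC 3 and control 2 on one side. At least the real 16 called lists came from 3 splits, the real one included, the highest other also being 16. Genes at an unadjusted p under 0.05 were most numerous in the real split, 2729 against at most 1645 in another. For genes listed at 0 in all libraries of one side and at 1 TPM or more in all of the other, 3 splits, the real one included, gave at least the real 12, and the highest other, 33, again set DIC 1, DIC 3 and control 2 apart, which points to a structure of the libraries that crosses the groups.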
